A study of Ginkgo biloba with 9 samples.

How the data were processed

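RNA sequencing was carried out on leaves of Ginkgo biloba, a seed plant grown for its leaf extracts, of the cultivar Fozhi at 3 planting densities, with 3 libraries each. CK is the control density of 20 plants per square metre, MD the moderate density of 40 and HD the high density of 80, per the labels. The replicate numbers come from the sample titles. No label says whether libraries of a density came from separate trees, from separate pools or from one pool, so p-values measure only the spread between these libraries, which may be technical.

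The authors deposited one table of FPKM (fragments per kilobase of gene length, scaled to library size), with one value per gene and library, per the file headers. The submitters' processing notes name CASAVA 1.8, TopHat2 and RSEM without roles. The genome build and the annotation are not given in the sources used here. All 9 value columns matched one sample title each, and 0 other columns were present. The table listed 41309 gene identifiers, of which 13961 were at 0 in every library. In the table, identifiers stand without gene names, and no table that pairs them with names was used here. For that reason the 31 gene lists drawn up beforehand, for pathways such as flavonoid and terpenoid synthesis, were not matched, and no list test was run. No coordinates were used here.

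Although FPKM are not counts, their steps held the read numbers. If a value is a whole number of reads divided by the gene length and a library size, the values of one gene are whole multiples of a gene-specific unit once each library is scaled by its relative depth. Relative depths were taken from low genes with equal read numbers in a pair of libraries (307 to 412 genes per pair), and the unit of each gene was the largest that made its values whole. Of the 21602 genes above 0 in every library, 100.0% came out whole within 0.001 reads plus the rounding of the deposited digits. Of 2000 of these genes whose values were moved at random by up to 5%, 5 came out whole. Gene lengths recovered in the same step were multiples of 3 in 86.9% of genes, against 33.3% by chance, with a median of 1191 nt. The recovered reads summed to between 14703230 and 22445283 per library. The library sizes by which the authors' FPKM were divided, as recovered with lengths in steps of 1 nt, were 0.972 to 1.042 times these sums, so the deposited values carry a scaling that differs from division by total reads. On simulated reads, the recovery returned 99.86% of 4334 genes above 0 in every library exactly. Genes at 0 in any library, including Gb_37031 and Gb_15706 named below, were in neither check.

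The test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1) for the 19854 genes with an FPKM of at least 1 in at least 3 libraries. One model was fitted to all 9 libraries without a replicate block. Contrasts were MD minus CK, HD minus CK, HD minus MD, and MD minus the mean of CK and HD. This last one is 0 where the log2 level changes by the same amount at each doubling of density. A moderated F test asked whether a gene differed among any of the densities. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. In simulated data with 200 changed genes and 19475 genes passing the filter, the MD against CK comparison recovered 10% of 1.2-fold, 60% of 1.5-fold, 92% of 2-fold and 96% of 4-fold changes, with 6 false calls. The HD against CK comparison recovered 10%, 58%, 90% and 96% of these, with 5 false calls. With so few changed genes the adjusted p is stricter than in the data, so these shares may not hold for the real comparisons.

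Which genes are named was fixed by a rule. With no names at hand, it took the 2 called identifiers with the largest rise and the 2 with the largest fall over the 3 pairwise comparisons. The groups, the contrasts, the filter, the pseudocount and this rule were fixed before the data were examined. The recovery of reads, the 4 classes of mean FPKM over the 9 libraries and the count of genes with 0 reads at one density and at least 10 in each library of another were chosen after the data were seen. Chance values for comparisons that share libraries came from 100 simulations of unchanged groups with each gene's fitted spread. Exact Poisson-based intervals of read ratios and exact binomial intervals are at the 95% level and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Read numbers within a density spread 2.11 to 2.57 times as much as Poisson counting (median squared difference). The intervals of read ratios may therefore be too narrow. Alternatives were another pseudocount, other filters, upper-quartile and quantile normalization, total-read scaling, robust variance estimates, a replicate block, a fit on each pair of groups alone, limma-voom on the recovered reads, a length correction, and the removal of single libraries. Python 3.11.15 with scipy 1.17.1 was used for the recovery and the exact tests.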

Results

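The leaf transcriptome was measured to ask how planting density affects gene expression in Ginkgo biloba grown for leaf harvest, as part of a study on leaf yield and active compounds. Leaves came from 3 densities, 20 (CK), 40 (MD) and 80 (HD) plants per square metre, with 3 libraries each. The libraries held between 14703230 and 22445283 reads in genes, as recovered from the steps of the FPKM values. Between 24031 and 24424 genes were above 0 per library, and between 18972 and 19141 reached an FPKM of 1. The libraries of one density lay close together. The median coefficient of variation over the 19854 tested genes was 7.59% in CK, 7.74% in MD and 7.75% in HD. For genes with a group mean of 100 FPKM or more it was 3.07%, 2.7% and 3.02%. Between pairs of libraries of one density, the median squared difference of read numbers was 2.11 to 2.57 times that of Poisson counting. In genes with 10000 or more reads in the pair it was 2.72 to 10.92 times. The lowest values were 2.72 for MD1 with MD2 and 2.85 for HD1 with HD2, and all other pairs had 5.32 or more.

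Between 20 and 40 plants per square metre, the first doubling of density, 7277 of 19854 genes differed (36.7%; limma, adjusted p under 0.05). Of these, 3576 genes were higher and 3701 lower in MD than in CK, a balance that turned under upper-quartile scaling (3768 and 3512) and total-read scaling (4102 and 3215). Most changes were small: the median absolute log2 fold change of called genes was 0.40, and the median standard error over all tested genes was 0.097. Changes of at least 2-fold were called for 407 higher and 230 lower genes, and of at least 4-fold for 51 and 34. The 3 MD libraries lay fully apart from the 3 CK libraries in 48.6% of tested genes, against 10% by chance. Genes with a mean below 10 FPKM contributed 266 of the 407 genes raised 2-fold and 139 of the 230 lowered.

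On the log2(FPKM + 1) scale, the gene with the largest rise in this comparison was Gb_36910, though Gb_37031 rose more with a pseudocount of 0.1 (8.55 against 8.44) and by limma-voom (9.44 against 8.62). Its level was 0.531 ± 0.450 FPKM in CK (SD, n = 3) and 176 ± 8.33 in MD (n = 3), a log2 fold change of 6.90 (SE 0.187, adjusted p = 1.28e-09). In HD it stood at 20.7 ± 3.68 FPKM, below MD by a log2 fold change of -3.05 (SE 0.187, adjusted p = 4.06e-07). The largest fall on the log2(FPKM + 1) scale was in Gb_15706, which had 29.3 ± 3.41 FPKM in CK and was nearly silent in MD, with 3 reads over the 3 MD libraries against 1105 in CK. The read ratio of CK to MD was 313 (exact 95% interval 107 to 1520), and the log2 fold change was -4.81 (SE 0.109, adjusted p = 2.68e-10). In HD the same gene was at 58.9 ± 3.25 FPKM, above CK by a log2 fold change of 0.99 (SE 0.109, adjusted p = 2.32e-05). What these genes encode is not known from the sources used here.

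In the widest contrast, 80 against 20 plants per square metre, 10324 genes differed (52% of those tested), with 5038 higher and 5286 lower in HD. Called changes had a median absolute log2 fold change of 0.46. At least 2-fold changes were called for 605 higher and 536 lower genes, and at least 4-fold for 61 and 69. The 2 groups did not overlap in 59.8% of genes, against 10% by chance. With each library scaled to its total reads in place of the authors' scaling, the split became 6379 higher and 4206 lower, a move from 48.8% to 60.3% higher, and under upper-quartile scaling it was 5680 and 4754. The median gene shifted by 0.08 on the log2 scale under total-read scaling.

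Gb_37031 had the largest rise in this comparison on the log2(FPKM + 1) scale and rose at both steps. It was almost absent from CK (0.085 ± 0.0999 FPKM, 4 reads in the 3 libraries), and reached 62.7 ± 1.17 FPKM in MD and 197 ± 2.33 in HD (SD, n = 3). The log2 fold change was 5.88 in MD and 7.52 in HD against CK (SE 0.067 for both, adjusted p = 2.83e-12 and 2.09e-13). From MD to HD it rose by a further 1.64 (adjusted p = 1.86e-08). By reads, HD exceeded CK 2280-fold (exact 95% interval 891 to 8380).

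**Figure D1:**
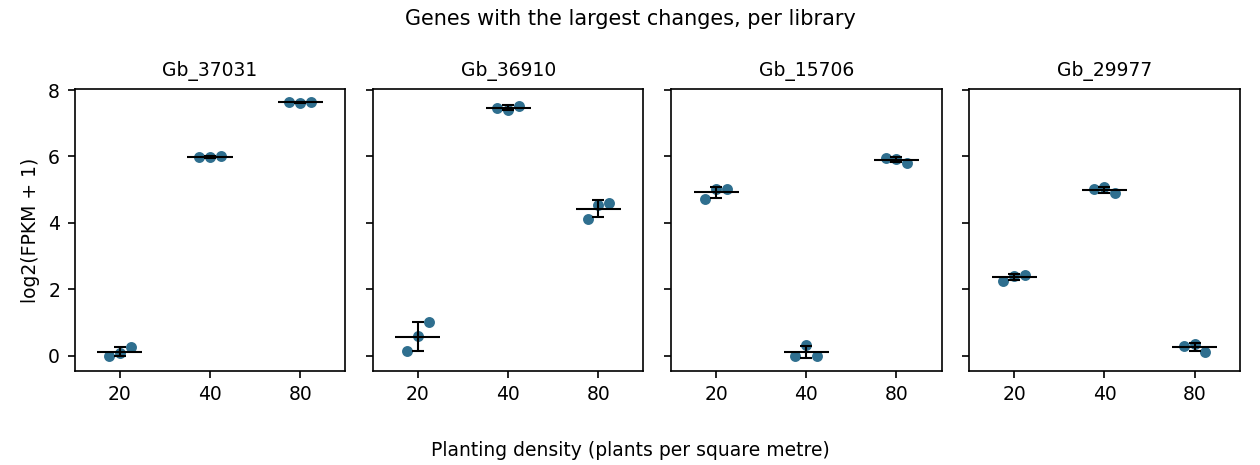
Expression of the 4 genes with the largest changes on that scale, as log2(FPKM + 1) against planting density; points are the 3 libraries, lines the group mean and bars the SD. Gb_37031 rose at both doublings of density, Gb_36910 and Gb_29977 were highest at 40 plants per square metre, and Gb_15706 was lowest there.

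Across the second doubling, from 40 to 80 plants per square metre, 8551 genes differed (43.1%), with 4059 higher and 4492 lower in HD than in MD. This balance turned under upper-quartile scaling (4543 and 4115), total-read scaling (4940 and 3821) and, narrowly, quantile normalization (4272 and 4247). At least 2-fold changes were called for 394 higher and 482 lower genes, and at least 4-fold for 38 and 83. The largest fall on the log2(FPKM + 1) scale was that of Gb_29977, from 31.0 ± 1.98 FPKM in MD to 0.191 ± 0.1 in HD (n = 3), a log2 fold change of -4.75 (SE 0.101, adjusted p = 1.82e-10). That gene was at 4.15 ± 0.313 FPKM in CK. Against CK it was higher in MD (log2 fold change 2.64, adjusted p = 1.61e-08) and lower in HD (log2 fold change -2.12, adjusted p = 3.68e-08). The largest rise at the second doubling on this scale was that of Gb_15706, nearly silent in MD, with a log2 fold change of 5.80 (SE 0.109, adjusted p = 6.63e-11).

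**Figure D2:**
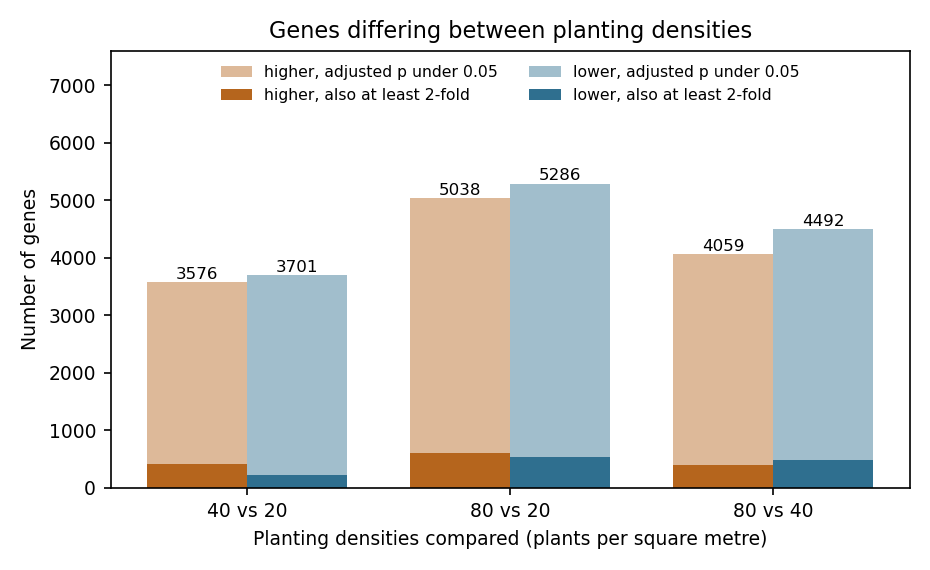
Number of genes higher or lower at the denser planting in each pairwise comparison, at an adjusted p under 0.05 (pale bars) and also at least 2-fold (dark bars). The comparison of 80 with 20 plants per square metre held the most called genes, 5038 higher and 5286 lower.

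Over all densities, 12175 genes (61.3%) differed by the moderated F test. Genes called at both doublings numbered 2436 with opposite directions and 1687 with the same direction. Independent lists of these lengths would give 1566 and 1568. Among genes that moved at least 2-fold at both doublings, 239 reversed and 28 kept their direction. Of the reversing genes, 157 peaked at MD and 82 had their lowest level there. Because MD enters both differences, unchanged groups alone give a correlation of -0.499 between the doublings in simulation. The observed correlation across genes was -0.32. The covariance was -0.0648, against -0.0080 for unchanged groups, a difference of -0.0569. Genes are not independent replicates. The 3 MD libraries were not divided between the doublings, since 1 part would be a single library. Part of the excess of opposite calls may therefore come from their sharing. Any true difference of MD from the other groups also enters both differences, with opposite signs, and the simulation does not remove it. A straight line in log2 density was rejected for 6606 genes (33.3%), with 3484 above and 3122 below the mean of CK and HD at MD.

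The genes called in MD and in HD against CK overlapped. Relative to CK, 2150 genes were higher and 2514 lower in both, where independent lists would share 907 and 985. Another 348 genes were higher in MD and lower in HD, and 284 the reverse. The fold changes correlated across genes with r = 0.529. Both comparisons use the same CK libraries, and unchanged groups gave r = 0.5 in simulation with a covariance of 0.00803. The observed covariance was 0.1196, which leaves 0.1115. The 3 CK libraries were not split between the comparisons, since 1 part would be a single library, so part of the excess of shared calls may come from the shared libraries. Any true difference of CK from the other groups also enters both comparisons, and neither baseline removes it. The overlap therefore does not separate a shared response to the denser plantings from a difference particular to the CK plants.

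The most abundant transcripts were mostly lower at the high density as deposited, though not under quantile normalization. Of 113 genes with a mean of 1000 FPKM or more, 73 were lower and 20 higher in HD than in CK, with a median log2 fold change of -0.194. In MD, 53 were lower and 34 higher than in CK, a lean that narrowed to 44 and 40 under total-read scaling and to 40 and 36 under quantile normalization. Quantile normalization, which gives every library one distribution, tipped the HD balance to 44 higher and 37 lower. Upper-quartile and total-read scaling kept more genes lower, with 65 and 57 lower genes against 23 and 31 higher ones. The summed level of the 113 genes was 400021 ± 7778 FPKM in CK, 398880 ± 1345 in MD and 330081 ± 1252 in HD (SD, n = 3). All HD libraries lay below all others (exact permutation test, two-sided p = 0.1 against CK and against MD, the smallest that 3 against 3 can give). The fall was 17.5% from CK to HD, and 12.3% under total-read scaling. Without the 10 genes with the largest falls it was 6.58%. The summed FPKM of all genes also fell as deposited, from 1082734 to 1097979 in the CK libraries to 996238 to 1001236 in the HD libraries. FPKM are divided by gene length, so short genes weigh more in such sums. The 17.5% is therefore a change of summed FPKM and not of the share of reads in these 113 genes. Genes of low abundance leaned the other way. Below 10 FPKM, 2160 genes were higher and 1617 lower in HD than in CK, and more were higher under all 4 scalings, though narrowly under quantile normalization (1868 against 1815).

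**Figure D3:**
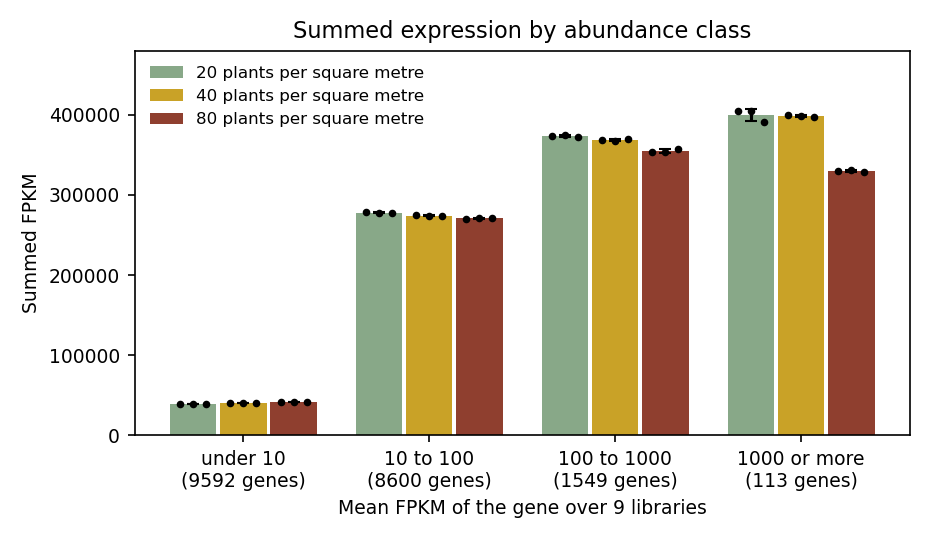
Summed FPKM of genes in 4 classes of mean abundance; bars are group means, whiskers the SD and points the 3 libraries of each density. In the class of 1000 FPKM or more the sum as deposited was 400021 at 20 plants per square metre and 330081 at 80, and the balance of called genes in this class tipped to 44 higher and 37 lower under quantile normalization.

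A small set of genes was present at some densities and absent at others. In 60 genes, all 3 libraries of one density had 0 recovered reads while each library of another had at least 10. The recovery of reads was checked only on genes above 0 in every library, so these genes lie outside that check. By pairs of densities, 16 genes were absent from CK and present in MD, and 21 were absent from CK and present in HD. In the other direction, 13 genes present in CK were absent from MD and 11 from HD. Between the denser plantings, 21 genes were absent from MD and present in HD, and 6 the reverse. A library with 0 reads for a gene still allows up to 3 reads, for counting error only.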

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

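The tests of the share of genes with MD as the odd one out, of mixed groupings, of the variance ratio and of the libraries numbered 3 were chosen after these or closely related values were seen. Groups of 3 libraries are too small for a search for outlying samples, so the results below are those in which the effect of one doubling of density differed from that of the other.

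Of the tested genes, 6606 departed from a straight line in log2 density (limma, adjusted p under 0.05), and 2436 had opposite called directions at the 2 doublings. The 4 named genes were each called in the first test. The log2 level at MD differed from the mean of CK and HD by 2.12 for Gb_37031, 4.97 for Gb_36910, -5.31 for Gb_15706 and 3.69 for Gb_29977.

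In 28 genes, either 1 density had 0 reads and each library of the others at least 10, or the reverse, and MD was the odd one out in 39.3% of them (11 genes, exact 95% interval 21.5% to 59.4%), CK in 8 and HD in 9. A steady rise or fall with density would keep MD between the others. The 11 genes with MD as the odd one out depart from it by their definition. The genes with CK or HD as the odd one out leave a rise or fall open, so the share decides nothing about it. Among all genes, 36 groupings that mixed the densities gave 0.0% as many absent and present pairs. Each mixed group held 1 library of every density, so genes with such a pair between densities could not give one there. The 0.0% therefore comes from the other genes only, in which mixed groups gave no such pair. It is no check of the genes with the pattern. Over all tested genes, the negative covariance of the doublings was restated as a ratio. The variance of HD minus CK without noise was 0.696 times the summed variances of the doublings (0.687 to 0.701 with single libraries left out). This lies below the 1 of independent steps and the 2 of steady changes, and above the 0.5 of 3 groups equally far apart. A ratio below 1 follows from the negative covariance reported above. It is therefore no separate test of fold changes that add up along the series. The negative covariance means that log2 changes at the 2 doublings partly cancelled across genes. A level particular to the MD plants would give the same, since MD enters both differences with opposite signs. Separate plant material at each density may give genes with 1 odd density, with a share of 33.3% for MD, inside the interval of the 39.3% seen. Nothing requires such material to lie equally far apart, and the spread between plant lots of one density is not known. The 0.696 therefore does not speak for or against it. Separate plant material cannot be told apart from a response to density that is not steady, which was not tested, because nothing in the labels separates the plants from the densities.

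Libraries of one density differed by a median of 2.32 times the Poisson spread. Both mates of a read pair counted singly may contribute up to 2 times, and the 53.2% of even numbers among 3859 counts of 1 to 20 (Wilson 95% interval 51.6% to 54.8%) are in line with this. In 1662 genes with a mean of 100 FPKM or more, the libraries numbered 3 deviated from numbers 1 and 2 alike in all 3 densities. The correlations across genes, which are not independent, were 0.349, 0.489 and 0.38. Equal numbers correlated less for number 1 (0.159, 0.206 and 0.119) and number 2 (0.179, -0.011 and 0.137). Unequal pairs of numbers 1 and 2 lay between 0.028 (CK2 with MD1) and 0.325 (CK1 with HD2). Deviations from a group mean cancel within a density, so a shared deviation of number 3 also draws numbers 1 and 2 together. Their values are therefore no independent comparison for number 3. A processing step shared by the 3 libraries numbered 3 may be behind the correlations of 0.349 and above. A trend of the number 3 deviations with gene length stays open. The rank correlations of -0.14, -0.11 and -0.19 lay between the bounds set for and against it. No biological explanation was tested.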

How the results depend on the processing

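Total-read scaling, limma-voom, the length correction, the removal of the libraries numbered 3 and averaged libraries were chosen after seeing the data. The direction and the call of each of the 4 named genes in each of the 3 pairwise comparisons were kept in all 264 recomputed fold changes. Counts of called genes stayed within 1.5 times of those reported under every other setting run except the added demand of a 2-fold change. That demand left 637 genes for MD against CK, 1141 for HD against CK, 876 for HD against MD and 489 for the departure from a straight line. Leaving out single libraries moved the correlation of the MD and HD responses to between 0.520 and 0.543, and a pseudocount of 0.1 moved it to 0.510. The SD of 3 such correlations, each from 1 library per density with the same number, was 0.0046. It is only a rough scale for these moves, since equal numbers were not treated as pairs. The replicate block gave 7307, 10270 and 8520 called genes in the pairwise comparisons, 12082 by the F test, 6632 for the departure and r = 0.529. Deviations from the group means correlated between -0.007 and 0.073 for equal numbers and between -0.052 and 0.043 for others over all tested genes, and in the 1662 genes of 100 FPKM or more between -0.011 and 0.489 for equal numbers and between -0.400 and 0.325 for others. In the latter genes, pairs were over 0.1 for numbers 1 and 3 but not all for number 2. The numbers were not treated as pairs, as fixed beforehand, because no label says that equal numbers share a plot or day. Of the 9 libraries, 5 correlated best with their own number in both other groups. Limma-voom on the recovered reads called 8052, 11070 and 9066 genes. Without the libraries numbered 3, 5548, 8570 and 6717 were called, and with MD1 and MD2 averaged and HD1 and HD2 averaged, 6657, 9732 and 6935. Of the calls, 95.3%, 96.8% and 92.5% kept their direction and their call after a trend with gene length was removed, which argues against such a trend as the reason for the calls. For each pairwise comparison, 1 of the 10 splits of the 6 libraries gave as many genes, the real one, and the highest other split gave 0; 10 splits are too few for a share under 0.05. For the F test and the departure, 1 of 100 splits each gave as many (12175 and 6606), the highest others 4539 and 4551. Libraries group by density, but plant lots may differ by chance. The planned tests of recovered reads with edgeR and DESeq2 were not run, so limma-voom was the only test of those reads, and the list tests were not run, since no table that pairs the identifiers with names was used here. Small changes were mostly missed in simulated data, where 10% of 1.2-fold changes were recovered in the MD and HD comparisons with CK; the effect of depth was not tested.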

Other observations

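The correlation of HD minus CK was chosen before its result was seen, after a first look at the calls, and the other correlations were run beside it. The identifiers carry numbers, and genes whose numbers follow each other changed together slightly more than other genes. The hypothesis was that such genes share a response. Over 10273 pairs of tested genes with consecutive numbers, the Spearman correlation of HD minus CK was 0.132, above the highest of 1000 shuffles (0.034). It was 0.118 for MD minus CK and 0.154 for HD minus MD, against highest shuffles of 0.031 and 0.033. The permutation p was 0.001 in each of these 3 comparisons, the smallest that 1000 shuffles can give. At 100 numbers apart the correlations were -0.007, 0.018 and -0.010 for HD minus CK, MD minus CK and HD minus MD. The order of the numbers is not explained in the sources used here, so neighbouring genes, copies of one gene that share reads, and other reasons for consecutive numbers may each contribute to the 0.132, and genes are not independent replicates.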
